A study of Homo sapiens with 4 samples.

How the data were processed

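Total RNA of cultured U87MG cells, an established human malignant glioma line, was measured on 4 Affymetrix Human Gene ST arrays, 1 array per sample. The cells carried aminopeptidase N (APN, also called CD13, encoded by ANPEP) with an EGFP label, either in its wild-type form or with the L243P substitution, which the labels call inactive. Each form had 2 replicates, which per the labels came from independent experiments. The array labels name 1 clone per form, so the clone and the APN form cannot be told apart. The p-values of single genes measure the spread between cultures of those clones only.

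Per the deposited note of the authors, the intensity values were obtained from the raw array files by RMA background correction, quantile normalization and RMA summarization per probe set, and were analysed in Rosetta Resolver. RMA is also the tool named in the submitters' processing notes, with no version given there. The deposited intensity values are linear and whole numbers, from 3 to 54600. The highest intensity differed between the arrays, so the deposited values do not share identical quantiles. The genome build is not given in the sources used here. Each signed fold, rank and estimated share of false positives of the authors' comparison table is a score of the authors, and the p-values beside them were made by the authors in Rosetta Resolver and with rank products in RankProdIt. Per the deposited note, the authors called probe sets at an estimated share of false positives (pfp) of 0.15 or lower. These columns were used only to describe the authors' own calls.

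The plan had assumed log2 values at full precision. The deposited intensities were therefore converted with log2, with a pseudocount of 0, since the lowest value was 3. The table of the complete data and the value table of the series matrix were identical. The table held 29085 probe sets, of which 21065 had 1 gene name, 57 a name of several words and 7963 no name. Tests ran over all probe sets, and genes were counted and named only from probe sets with 1 name. Of the 19522 genes, 984 had more than 1 probe set, and the probe set with the highest mean was kept for each of them. Names were updated through a gene table of the GRCh38.p14 assembly: 15631 genes matched a current symbol, 2518 an older symbol and 1373 none, for which the file's name was kept. That table was used only for names, chromosomes and the order of neighbouring genes, and no coordinates are given.

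L243P and wild-type APN arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term) on all 4 arrays. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. An exact permutation of 2 arrays against 2 has 3 splits and cannot go below p = 0.333, so no such test is given. The number of arrays limits the precision of every value. Rounding to whole numbers left 875 probe sets with no spread within either group, 834 of them among the dimmest 33.3%. With these probe sets the prior degrees of freedom that limma estimates were 1.13. One of the alternatives left out the dimmest 33.3% of probe sets, which kept 19390 probe sets and 15189 genes with a mean intensity of at least 22.7, and gave prior degrees of freedom of 3.35. The fit over all probe sets remains the main result, and its counts are given first. In the text, genes are said to rise or fall only where they passed the threshold with the dimmest probe sets left out. The choice to describe genes from that fit was made after both counts had been seen.

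The fit was tested on simulated arrays drawn from the levels of the real probe sets. Their spreads were scattered at random around the median spread of the probe sets above the dimmest 33.3%. All changed probe sets were taken from above the dimmest 33.3%, so the shares recovered say nothing about changes among the dimmest. Without rounding, the fit over all 29085 probe sets recovered 77.6% of probe sets changed by 1 log2 unit and 100% of those changed by 2 or by 3. After rounding, the same fit recovered 0%, 44.8% and 56.1%. With the dimmest probe sets left out, it recovered 64.2%, 91% and 80.3% of all changed probe sets, with 3 false calls among 19394 probe sets tested. A trend with a robust prior over all rounded probe sets recovered 64.2%, 98.5% and 100%, as many or more than the fit used to describe genes, with 1 false call.

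Gene lists, 42 in all, were written before the data were examined, as were the comparisons, the alternatives and the rule for named genes. Each list was tested with limma's camera with a preset correlation of 0.01 between genes, over all genes and with Benjamini-Hochberg adjustment over the lists. At that setting camera sets the genes of a list against the other genes, so its p-value does not measure the spread between cultures. Beside it stand camera with an estimated correlation and fry. With an estimated correlation camera uses the few residual degrees of freedom of 4 arrays, so its power is low. Every list then had an adjusted p of 0.622 or more. The estimate was 0.44 for cholesterol synthesis and 0.24 for the hypoxia response. It was below the preset for MHC class I (-0.00022), endoplasmic reticulum stress (-0.032) and glutathione (-0.014). A call lost this way does not by itself show that the members are correlated. On simulated arrays in which only the list of DNA replication genes was shifted, by 0.5 log2 units, camera with the preset correlation called that list and 0 of the others. The simulated genes varied independently of each other, so this does not show how often correlated genes give false calls. In the real arrays the estimated correlation was 0.54 for DNA replication and 0.74 for mitosis. Log2 changes are L243P minus wild type. Standard errors (SE) of single genes and adjusted p-values are those of the fit with the dimmest probe sets left out, unless stated otherwise.

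The rule for named genes took ANPEP first. Since no gene passed over all probe sets, it then took the 10 genes per direction with the smallest unadjusted p. For each list described it took up to 4 members past the threshold with the smallest p, or otherwise up to 2 with the largest change. Other genes named were chosen after their values were seen. Some genes and 1 of the gene lists past the threshold are not reported here, though counts over all genes or lists include them. Genes of families with near-identical sequences, such as histones, and pseudogenes are uncertain, since probes can read several copies.

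Alternatives were the replicate number as a block, a repeated quantile normalization, median centring, the mean of a gene's probe sets, a trend or a robust fit in eBayes, stricter thresholds, and each array left out in turn. With 1 array left out, the lone array of its group is assumed to vary like the other group. For lists, camera on ranks was added to these. For chromosomes, the median log2 change was set against 10000 random gene sets matched on level in 10 bins. That p-value too rests on the spread between genes, not on that between cultures. Python 3.11.15 drew the plots. The authors' note and the averaged intensities were not tested.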

Results

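Gene expression was profiled in U87MG glioma cells that carried EGFP-labelled aminopeptidase N (APN, CD13), a membrane enzyme that removes amino acids from the N-terminus of peptides. Cells of a clone with the wild-type enzyme (2 arrays) were set against cells of a clone with the inactive L243P form (2 arrays). The title of the series names tumour cell proliferation and the formation of new vessels as its subject, so genes of the cell cycle and of angiogenesis were examined along with the whole transcriptome. The median intensity was 50 and 48 on the wild-type arrays (replicates 1 and 2) and 46 and 50 on the L243P arrays. The log2 intensities correlated across probe sets, which are not independent replicates, at r = 0.993 between the wild-type arrays, at 0.9948 between the L243P arrays and at 0.9897 to 0.9913 between the groups. The median absolute log2 difference was 0.16 between the wild-type arrays, 0.128 between the L243P arrays and 0.155 to 0.183 between the groups. By that measure the wild-type arrays were no closer to each other than to some L243P arrays.

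ANPEP, on chromosome 15, was among the bright genes on all 4 arrays. Its intensity was 8447 and 9103 with wild-type APN and 6439 and 7122 with L243P APN, a log2 change of -0.37 (SE 0.11, n = 2 per group). The adjusted p was 0.305 over all probe sets and 0.247 with the dimmest probe sets left out, so the difference did not pass the threshold. Both clones carry an APN transgene, and whether the probe set reads it is not known here, so this level does not check the labels.

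Cells with L243P APN had less RNA of UBE2K, of a group of neighbouring histone genes, and of POSTN, SERPINB2 and HAS2, and more of CHI3L1, PLXDC1 and LBP. Over all 29085 probe sets, limma called 0 genes higher and 0 lower, with a smallest adjusted p of 0.263. At an unadjusted p under 0.05 the same fit gave 1295 genes higher and 1481 lower, and with a trend and a robust prior it called 81 higher and 102 lower. With the dimmest 33.3% of probe sets left out, 25 genes rose and 45 fell among 15189, and all 70 of these were also called with the trend and the robust prior over all probe sets. At least 2-fold differences were measured for 40 genes higher and 69 lower in L243P, each with no overlap between the groups. Across all genes the groups did not overlap for 7406 (37.9%), where chance gives 33.3% for values without ties. Ties between the rounded values were counted as overlap, so the share by chance is lower than that here.

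Among the genes that fell, UBE2K, a ubiquitin-conjugating enzyme, had the largest measured change, from 489 and 526 with wild-type APN to 19 and 16 with L243P APN (log2 change -4.86, SE 0.13, adjusted p = 0.00191). H1-4 and H1-2, linker histones named HIST1H1E and HIST1H1C in the files, fell, with log2 changes of -3.82 (SE 0.15, adjusted p = 0.00475) and -2.51 (SE 0.12, adjusted p = 0.00715). POSTN, which encodes the matrix protein periostin, dropped from 257 and 312 to 23 and 23, a log2 change of -3.62 (SE 0.13, adjusted p = 0.0046). SERPINB2, an inhibitor of plasminogen activators, dropped from 1033 and 1001 to 156 and 165, a log2 change of -2.66 (SE 0.10, adjusted p = 0.0046). HAS2, a hyaluronan synthase, fell by 2.40 on the log2 scale (SE 0.11, adjusted p = 0.00582). ANKRD1, a transcript induced by YAP and TAZ, fell by 1.82 (SE 0.11, adjusted p = 0.00985), and SCG2, which encodes the granin secretogranin II, fell by 1.65 (SE 0.11, adjusted p = 0.0119). ANTXR2, a receptor of anthrax toxin, fell by 1.44 (SE 0.10, adjusted p = 0.015) and FRYL by 1.22 (SE 0.10, adjusted p = 0.0259). UBE2K, ANTXR2 and FRYL lie in a stretch of chromosome 4 in which 230 of 261 genes above the dimmest probe sets were lower in L243P, and UBE2K has 1 probe set on the array.

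Of the genes that rose, LBP, which encodes lipopolysaccharide-binding protein, went from 20 and 19 with wild-type APN to 199 and 153 with L243P APN, a log2 change of 3.16 (SE 0.15, adjusted p = 0.00715). PLXDC1, known as a marker of tumour endothelium, went from 52 and 51 to 313 and 263, a log2 change of 2.48 (SE 0.12, adjusted p = 0.0075). CHI3L1, a secreted glycoprotein used as a marker of mesenchymal glioma, rose from 1161 and 1081 to 4186 and 4636, a log2 change of 1.98 (SE 0.11, adjusted p = 0.00858). TUSC3, a subunit of the oligosaccharyltransferase complex, rose by 1.82 (SE 0.12, adjusted p = 0.0119). PCOLCE, which enhances the processing of procollagens, rose by 1.38 (SE 0.10, adjusted p = 0.0159). The pseudogene RPSAP52 rose by 1.28, PADI3, a peptidylarginine deiminase, by 1.27, MYL9, a myosin regulatory light chain, by 1.10, and FN1, which encodes fibronectin, by 0.93. ERMP1, a peptidase of the endoplasmic reticulum, rose from 99 and 97 to 201 and 192, which is 2-fold. The SE of these 5 changes was 0.10 and their adjusted p lay between 0.0253 and 0.0437. UBE2K and H1-2 with L243P APN and LBP with wild-type APN measured below 22.7, the lowest mean kept with the dimmest probe sets left out, and POSTN and HAS2 with L243P APN measured close to it. These levels are not shown to lie above background, so the sizes of these 5 changes and their SE are not exact. Each of the 20 genes had an adjusted p of 0.263 over all probe sets.

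**Figure D1:**
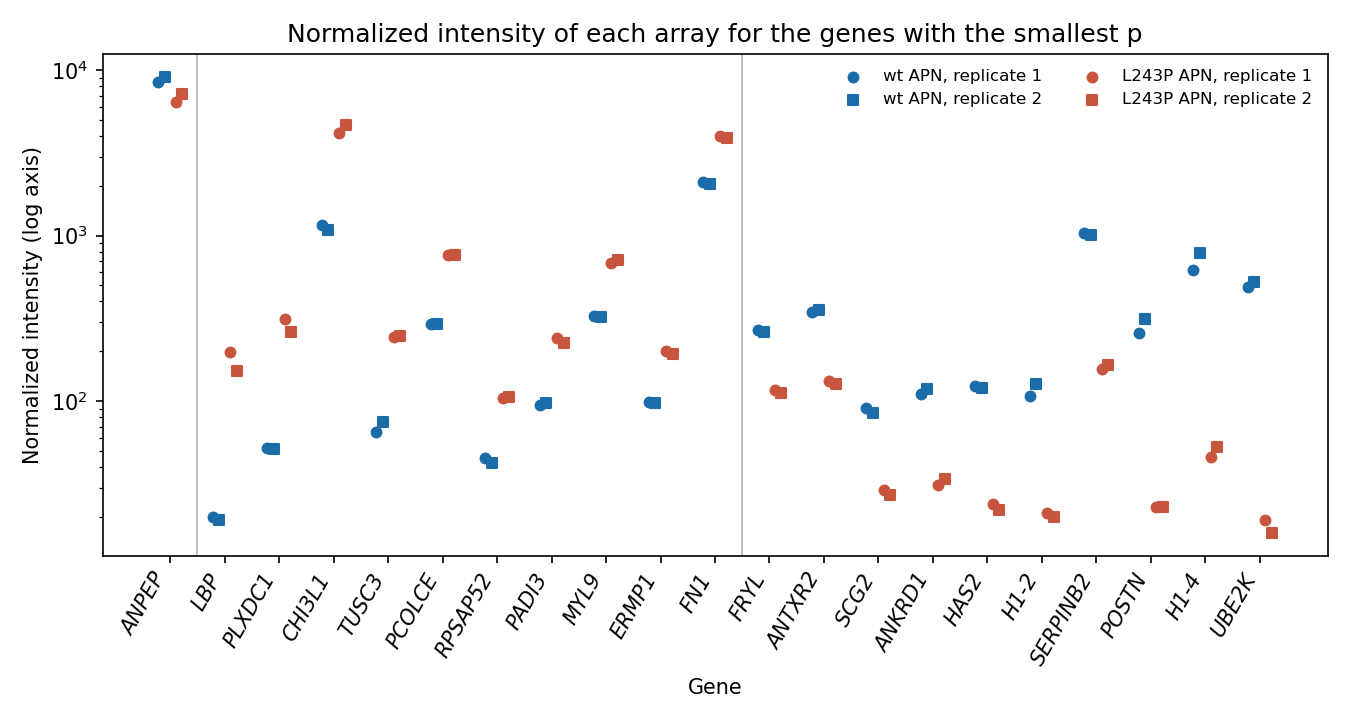
Normalized intensity (log axis) of each of the 4 arrays for ANPEP and for the 10 genes per direction with the smallest unadjusted p, with wild-type APN in blue, L243P APN in red, circles for replicate 1 and squares for replicate 2. The arrays of the groups do not overlap for any of the genes drawn, and UBE2K spans the widest range, from 526 to 16.

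These calls rest on 4 arrays. For each of the 70 called genes both L243P arrays lie beyond both wild-type arrays. Leaving out 1 array therefore could not reverse a direction. With wild-type replicate 1, wild-type replicate 2, L243P replicate 1 or L243P replicate 2 left out, 0 of the 70 genes passed, although all 70 kept their direction in each case. With the dimmest probe sets left out, the balance of directions differed between settings: 25 genes higher and 45 lower as deposited, 51 and 72 with a repeated quantile normalization, 154 and 145 with each array centred on its median, and 155 and 135 with a trend and no rescaling.

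Genes of the hypoxia response were lower in L243P APN cells. Of 30 measured members 27 were lower, with a median log2 change of -0.33 (camera, adjusted p = 4.41e-10). The call was lost with an estimated correlation (adjusted p = 0.622). The median of the list was -0.44 without wild-type replicate 1 and -0.25 without wild-type replicate 2. NDRG1 fell by 1.22 on the log2 scale, from 797 and 830 to 360 and 341 (SE 0.10, adjusted p = 0.0259). CA9, a carbonic anhydrase of the cell surface, fell by 1.31 (SE 0.12, adjusted p = 0.0298) and BNIP3, a mitochondrial protein of autophagy and cell death, by 0.97 (SE 0.10, adjusted p = 0.0437). No other member passed, 0 rose, and adjusted over the list alone 14 fell. LOX, the lysyl oxidase that crosslinks collagen, measured 946 and 1400 with wild-type APN and 437 and 466 with L243P APN, and had an adjusted p of 0.0837.

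Glycolysis genes, some of them shared with the hypoxia list, had a median log2 change of -0.25 over 22 members, of which 18 were lower (camera, adjusted p = 0.00237). With an estimated correlation the adjusted p was 0.622. No member passed over all genes, and 3 fell adjusted over the list alone. The glucose transporter SLC2A1 measured 453 and 592 with wild-type APN and 229 and 220 with L243P APN, and the log2 change of PFKFB3, which makes an activator of glycolysis, was -0.67. SLC2A1 and PFKFB3 are both also members of the hypoxia list, and the glycolysis list was not tested without the shared genes. Without L243P replicate 1 the median of the glycolysis list was -0.16. Oxidative phosphorylation genes had a median of 0.05 over 46 members (adjusted p = 0.122), with SDHC at 0.79 and ATP5F1C at 0.45, 0 called over all genes, and 1 that rose adjusted over the list alone. Without wild-type replicate 2 that list had a median of 0.10 and was called (adjusted p = 0.00162), whereas without wild-type replicate 1 the median was 0.004 (adjusted p = 0.994). With an estimated correlation and all 4 arrays the list had an adjusted p of 0.878. SDHC lies in a stretch of chromosome 1 from HAPLN2 to CCNQP1, in which 161 of 195 genes above the dimmest probe sets were higher in L243P.

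Genes of NF-kB and inflammatory cytokines were lower as a list, with a median of -0.24 over 42 members, of which 31 were lower (camera, adjusted p = 0.00541, and adjusted p = 0.686 with an estimated correlation). CXCL8, the chemokine interleukin 8, fell from 143 and 100 to 31 and 33 (log2 change -1.90, SE 0.19, adjusted p = 0.0367). IL1B measured 310 and 168 with wild-type APN and 74 and 67 with L243P APN (adjusted p = 0.105). Of the members, 8 fell and 4 rose adjusted over the list alone. The call of the list was lost without wild-type replicate 1 (median -0.14, adjusted p = 0.261) and without L243P replicate 2 (median -0.20, adjusted p = 0.0815). CXCL8 lies in the stretch of chromosome 4 named above, and without the genes of that stretch and of stretches of chromosomes 1 and 6 the list had a median of -0.19 over 35 members (adjusted p = 0.0755).

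Histone genes had a median of -0.30 over 16 members, 14 of them lower (camera, adjusted p = 0.000466, and adjusted p = 0.622 with an estimated correlation). H1-4, H1-2 and the core histone H2AC6 fell, the last with a log2 change of -1.60 (SE 0.12, adjusted p = 0.0241), and adjusted over the list alone 5 fell and 1 rose. These genes are neighbours on chromosome 6, and without the genes of the stretches on chromosomes 1, 4 and 6 the list was not called (9 members, median -0.19, adjusted p = 0.269). Ribosomal protein genes had a median of -0.08 over 43 members, with 0 called members and 36 lower (camera, adjusted p = 0.0338, and adjusted p = 0.819 with an estimated correlation), RPL34 at -0.53 and RPS23 at -0.43. That call was lost without wild-type replicate 2 (median -0.04, adjusted p = 0.426), without L243P replicate 1 (median -0.05, adjusted p = 0.149), with median centring (adjusted p = 0.112) and with a repeated quantile normalization (adjusted p = 0.131).

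Genes of cholesterol synthesis were higher in L243P APN cells. Of 30 measured members 28 were higher, with a median log2 change of 0.59 (camera, adjusted p = 4.61e-15). With an estimated correlation the call was lost (adjusted p = 0.622). No member passed over all genes, and adjusted over the list alone 20 rose and 0 fell. IDI1, an isomerase of the isoprenoid pathway, measured 309 and 256 with wild-type APN and 594 and 531 with L243P APN, a 2-fold difference (SE 0.14 on the log2 scale, adjusted p = 0.0721). The fatty acid desaturase SCD measured 1889 and 807 with wild-type APN, 3127 and 3037 with L243P APN (log2 change 1.32, SE 0.39, adjusted p = 0.242). The size of the median of the list depended on the wild-type array left out. It was 0.75 without wild-type replicate 1 and 0.37 without wild-type replicate 2.

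Genes of MHC class I and antigen processing had a median of 0.13 over 22 members, 16 of them higher (camera, adjusted p = 0.00406, and adjusted p = 0.622 with an estimated correlation). No member passed, 0 rose adjusted over the list alone, and PSMB9 was at 0.30 and HLA-F at 0.29. The call was lost without L243P replicate 1 (median 0.15, adjusted p = 0.089). Smooth muscle and contractile genes had a median of 0.10 over 22 members, 17 of them higher (camera, adjusted p = 0.00574, and adjusted p = 0.622 with an estimated correlation). MYL9 rose, and adjusted over the list alone 3 rose and 1 fell. That call was lost without L243P replicate 2 (median 0.06, adjusted p = 0.0558). Genes of glutathione metabolism and the NRF2 response had a median of 0.08 over 46 members, 27 of them higher (camera, adjusted p = 0.0159, and adjusted p = 0.622 with an estimated correlation). HMOX1, the haem oxygenase, rose from 679 and 808 to 1613 and 1826 (log2 change 1.21, SE 0.14, adjusted p = 0.0487), and adjusted over the list alone 3 rose. That list was called without wild-type replicate 1 but not without wild-type replicate 2 (median 0.06, adjusted p = 0.0596), L243P replicate 1 (0.08, adjusted p = 0.101) or L243P replicate 2 (0.05, adjusted p = 0.0558).

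Genes of endoplasmic reticulum stress had a median of 0.12 over 32 members, 23 of them higher (camera, adjusted p = 0.0253, and adjusted p = 0.622 with an estimated correlation). No member passed, also adjusted over the list alone. ATF6, a sensor of that stress, was at 0.66 and DNAJC3, a chaperone partner, at 0.55. ATF6 lies in the same stretch of chromosome 1 as SDHC. The call was lost without the dimmest probe sets (adjusted p = 0.0797), without wild-type replicate 2 (median 0.13, adjusted p = 0.272), without L243P replicate 1 (median 0.11, adjusted p = 0.13), with median centring (adjusted p = 0.0876) and with a repeated quantile normalization (adjusted p = 0.0887). The test fry, which asks whether the genes of a list moved one way on balance, called none of the 42 lists, with a smallest false discovery rate of 0.0982.

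**Figure D2:**
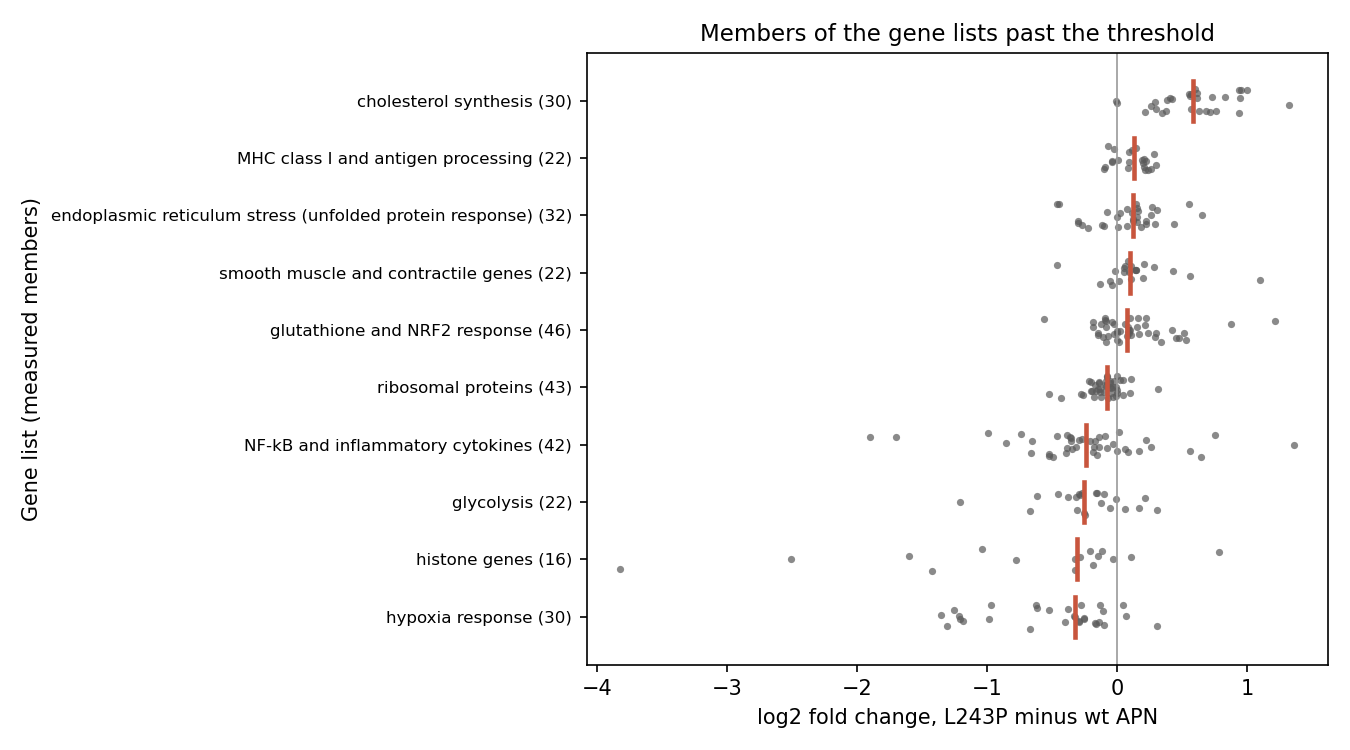
Log2 change, L243P minus wild-type APN, of each measured member (grey points) of 10 gene lists past the threshold in camera with the preset correlation, with the median of each list as a red bar and the number of measured members in brackets. Cholesterol synthesis has the highest median, 0.59 over 30 members, and the hypoxia response the lowest, -0.33 over 30 members.

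Proliferation and vessel formation, the subject of the series, were examined with lists of their own. Genes of DNA replication had a median of -0.08 over 51 members, of which 34 were lower (camera, adjusted p = 0.211), and genes of mitosis had a median of 0.03 over 59 members, of which 36 were higher (adjusted p = 0.225). No member of either list passed, also adjusted over the list alone. SLBP was at -0.58 and the helicase subunit MCM2 at -0.38, KIF14 at 0.75 and NUF2 at 0.69. SLBP lies in the stretch of chromosome 4 and NUF2 in that of chromosome 1. The direction of both lists depended on the wild-type array kept. Without wild-type replicate 1 the median was -0.13 for mitosis (adjusted p = 0.00224) and -0.20 for DNA replication (adjusted p = 9.64e-06), and without wild-type replicate 2 it was 0.22 (adjusted p = 2.23e-08) and 0.04 (adjusted p = 0.3), so mitosis was called in opposite directions. With an estimated correlation and all 4 arrays the adjusted p was 0.995 for both lists. Among cyclins, inhibitors of cyclin-dependent kinases and other regulators of the G1 phase (24 measured, median -0.06, adjusted p = 0.294), CCND1, which encodes cyclin D1, fell from 1743 and 1537 to 725 and 729 (log2 change -1.17, SE 0.11, adjusted p = 0.0352). CCND1 was the only member to pass, also adjusted over the list alone.

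Angiogenic factors and receptors had a median of -0.08 over 49 members, 30 of them lower, and were not called as a list (adjusted p = 0.225). CXCL8 fell, 37 other members tested did not pass, and adjusted over the list alone 6 fell and 1 rose. ADM, which encodes the vasoactive peptide adrenomedullin, measured 448 and 574 with wild-type APN and 215 and 232 with L243P APN (adjusted p = 0.0667). VEGFA, named after its values were seen, measured 603 and 654 with wild-type APN and 397 and 419 with L243P APN (adjusted p = 0.104). ADM and VEGFA are also members of the hypoxia list described above. Angiogenesis inhibitors had a median of -0.03 over 22 members (adjusted p = 0.924). No inhibitor passed over all genes, and 1 rose and 2 fell adjusted over the list alone. The metalloproteinase inhibitor TIMP2 was at 0.78 and the protease ADAMTS1 at -0.65.

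Genes of the extracellular matrix moved in both directions. Of 41 matrix glycoprotein and proteoglycan genes tested, FN1 and LAMA4, a laminin chain, rose, while POSTN, HAS2 and the fibrillin gene FBN2 fell, and 36 did not pass (50 measured, median -0.03, adjusted p = 0.764). The log2 change was 1.52 for LAMA4 (SE 0.16, adjusted p = 0.0437) and -1.18 for FBN2 (SE 0.12, adjusted p = 0.0409). In this list 7 rose and 7 fell adjusted over the list alone. Among matrix proteases and their inhibitors (45 measured, median -0.03, adjusted p = 0.454), SERPINB2 and the stromelysin MMP3 were among the members that fell. MMP3 changed from 5455 and 6475 to 2665 and 2627 (log2 change -1.17, SE 0.12, adjusted p = 0.0437). Adjusted over the list alone 4 rose and 6 fell. Collagens (25 measured, median -0.01, adjusted p = 0.858) had 0 members past the threshold, with COL12A1 at -0.61 and COL1A1 at 0.42, and 1 fell adjusted over the list alone. Of 33 integrins and adhesion receptors tested, ITGA4 fell (log2 change -1.16, SE 0.12, adjusted p = 0.0367, with a dim level in L243P), and the list was not called (40 measured, median -0.08, adjusted p = 0.24). Among them 1 rose and 3 fell adjusted over the list alone.

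Other aminopeptidases and membrane peptidases did not differ as a list (39 measured, median 0, adjusted p = 0.993). Of the 32 above the dimmest probe sets 0 passed, also adjusted over the list alone, with LAP3, a leucine aminopeptidase, at -0.63. CPE, a carboxypeptidase among the dimmest probe sets, was at -0.95 and passed only in the fit over all probe sets adjusted over the list alone (adjusted p = 0.0178). LAP3 lies in the stretch of chromosome 4. Markers of other cell types were not called, with adjusted p of 0.993 for endothelial cells (14 measured), 0.909 for macrophages and microglia (16), 0.606 for neurons (16), 0.999 for epithelial cells (15) and 0.225 for oligodendrocytes (8), and no marker passed over all genes. The count adjusted over the list alone was 2 neuron markers that rose and 1 oligodendrocyte marker that fell. For collagens, peptidases and epithelial markers camera's direction was higher while the median of the list was at or below 0. CD68, at 1932 and 1871 with wild-type APN and 2406 and 2569 with L243P APN, is also expressed by cells other than macrophages.

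The authors' deposited table of rank products held 148 probe sets lower and 128 higher in L243P APN cells at their limit of 0.15. Of these 276 probe sets in the authors' deposited table, 248 were above the dimmest 33.3%. All 82 probe sets that passed here with the dimmest ones left out were among them, with the same direction, where independent lists of these sizes would share 1.05. Both sets of calls come from the same 4 arrays, so the overlap is not independent evidence. The authors' deposited gene summary held 224 genes, 101 with a positive and 123 with a negative fold.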

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

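The combinations with the dimmest 33.3% left out, the random draws against rounding, the removal of probe sets with no spread, the crossed pairing and the removal of genes of chromosome stretches were chosen after seeing the data. Over all probe sets, where 0 genes were called in either direction, median centring gave 153 higher and 155 lower, a trend with a robust prior 81 and 102, leaving out the dimmest probe sets 25 and 45, and leaving out the 875 probe sets with no spread within either group 102 and 148. A uniform draw of up to 0.5 either way added to each intensity gave medians of 33 higher and 59.5 lower over 20 draws (29 to 35 and 51 to 62). The other alternatives over all probe sets gave 0. Because the removal of probe sets with no spread and the draws each brought calls back, rounding is a cause of the count of 0. With the dimmest probe sets left out, where 25 genes were higher and 45 lower, a repeated quantile normalization gave 51 and 72, median centring 154 and 145, a trend 155 and 135, a trend with a robust prior 227 and 191, and an adjusted p under 0.01 gave 3 and 10. Leaving out 1 array at a time gave 0 to 0 in both directions, with fewer samples. For lists, 5 higher and 6 lower, an estimated correlation gave 0 and 0, and leaving out 1 array at a time gave 2 to 6 higher and 4 to 8 lower. The cause of the other moves was not tested.

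With the replicate number as a block and the dimmest probe sets left out, 7 genes were higher and 21 lower, all 28 of them among the 70, and over all probe sets 0. The block changed no list call. The labels do not say that a number marks a shared day. The deviations of same-numbered arrays correlated at -0.16 (-0.26 with the dimmest probe sets left out), so the numbers were not taken as pairs. With 2 arrays per group the deviations mirror each other, so arrays of opposite number deviated alike to the same degree. Across the groups the median absolute log2 difference was 0.155 and 0.16 for opposite numbers and 0.183 and 0.17 for same numbers. The replicate pairs given below for chromosomes and stretches set same-numbered arrays against each other only as a split of the arrays. The crossed split, which pairs arrays that deviate alike, is not given for them. How far differences between the replicate pairs rest on the split was not tested. With the pairing crossed, 5 genes were higher and 17 lower with the dimmest probe sets left out, and 5 lists were higher and 5 lower. The ribosomal protein list lost its call then.

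The 98 single genes named by the rule kept their direction in all 876 values under the alternatives. Apart from ANPEP they were taken for a small p or a large change, so this largely restates the choice. The log2 change of ANPEP lay between -0.45 and -0.30 with 1 array left out and did not pass in any alternative. The number of chromosomes with a shifted median was 10, and 10 or 11 under the alternatives, but these were not the same chromosomes. Of the 10, 2 passed in both replicate pairs with medians of the same sign as over all arrays, chromosome 4 (-0.164 and -0.193 in pairs 1 and 2) and chromosome 8. Chromosomes 1 (0 and 0.1) and 2 (0 and -0.016) passed in both with a median of 0 in pair 1. A median was tested against random sets, not against 0, so a median of 0 that passed does not show an absent shift. The stretches of chromosome 1 from NBPF8, HAPLN2 and GARIN4, delimited below on these arrays, had medians of 0.226, 0.368 and 0.279 in pair 1. Chromosome 19 passed in both with opposite signs (-0.126 and 0.037). Chromosomes 7 and 13 had a median of 0 in pair 2 and did not pass there. Among rounded values such a median can tie with the random sets, and a tie cannot pass, so this is no evidence against a shift. Chromosomes 16 (-0.08 and 0.045) and 22 (-0.078 and 0.044), not among the 10, also passed in both pairs with opposite signs. Dim probe sets limit what can be seen, since a step of 1 intensity unit is a large part of their level.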

Other observations

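Several lists not described above had single members that fell in L243P APN cells, and none of these lists was called. In the list of TGF-beta and BMP signalling (43 measured, median log2 change -0.06, camera adjusted p = 0.225), BAMBI, a decoy receptor of that pathway, fell from 230 and 326 to 63 and 63 (log2 change -2.12, SE 0.18, adjusted p = 0.0275). Adjusted over the list alone 4 of its members fell. Of growth factor receptors and ligands (35 measured, median -0.11, adjusted p = 0.0884), EREG, the EGF receptor ligand epiregulin, fell (log2 change -1.34, SE 0.11, adjusted p = 0.0259), and adjusted over the list alone 7 fell and 1 rose. EREG lies in the stretch of chromosome 4. RNF43, a ubiquitin ligase that acts on WNT receptors, fell (log2 change -0.99, SE 0.10, adjusted p = 0.0367; WNT pathway, 38 measured, adjusted p = 0.708), as did the cancer-testis antigen MAGEC2, from 84 and 87 to 14 and 21, a dim level (adjusted p = 0.0298; list of 30 measured, adjusted p = 0.863). ANKRD1 was the only early target of YAP, TAZ and SRF to pass (17 measured, adjusted p = 0.225), CCND1 the only ERK feedback target (18 measured, adjusted p = 0.219) and BNIP3 the only apoptosis regulator (33 measured, adjusted p = 0.225). Of the 28 mesenchymal glioma markers tested, CHI3L1 and FN1 rose and 25 did not pass (adjusted p of the list 0.522). Adjusted over the list alone the counts of members that rose and fell were 3 and 1 for the WNT pathway, 0 and 1 for cancer-testis antigens, 0 and 1 for YAP, TAZ and SRF targets, 1 and 1 for ERK feedback targets, 2 and 6 for apoptosis regulators, and 2 and 4 for mesenchymal glioma markers.

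No member passed in the lists of glial and neural progenitor markers (37 measured, adjusted p = 0.931), immediate early genes (25 measured, adjusted p = 0.777), the type I interferon response (43 measured, adjusted p = 0.764), the amino acid and ATF4 response (38 measured, adjusted p = 0.452), the angiotensin and kinin system (20 measured, adjusted p = 0.233), HOX genes (35 measured, adjusted p = 0.307), or heat shock and proteasome genes (29 measured, adjusted p = 0.316). Adjusted over the list alone 4 progenitor markers rose and 1 fell, 1 interferon gene rose and 2 fell, 3 ATF4 genes fell and 2 HOX genes rose, and 0 changed in the other lists of this group. Without wild-type replicate 1 the HOX list was called higher (median 0.07, adjusted p = 0.0459) and the heat shock and proteasome list lower (median -0.18, adjusted p = 0.000321). Without wild-type replicate 2 their medians were -0.05 (adjusted p = 0.756) and 0.02 (adjusted p = 0.426), and that of the HOX list was -0.04 without L243P replicate 2, so the direction depended on the arrays kept. With an estimated correlation and all 4 arrays the adjusted p was 0.995 for both lists. For interferon genes and cancer-testis antigens the median and camera's direction were higher while the mean was below 0. Genes outside the rule, chosen after their values were seen, included PCSK2, a prohormone convertase, which rose from 64 and 48 to 360 and 274 (log2 change 2.50, SE 0.20, adjusted p = 0.0253), and IL13RA2, a receptor of interleukin 13 found on gliomas, which fell from 202 and 276 to 53 and 43 (log2 change -2.31, SE 0.19, adjusted p = 0.0259).

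The test of chromosomes and the removal of dim probe sets were planned. The stretches and the tests on them were chosen after seeing the data, although the bounds for the gene lists without the stretches were set before that result was seen. The median log2 change of the 688 genes of chromosome 4 was -0.145, with 75.7% of them lower in L243P (adjusted p = 0.00058, which rests on the smallest p that 10000 random sets can give, 1e-04). For the 1902 genes of chromosome 1 it was 0.038, with the same adjusted p. Medians of 8 other chromosomes also passed, but camera called chromosomes 4 (adjusted p = 5.34e-10) and 1 (adjusted p = 0.00019) alone. Stretches of chromosomes 1 and 4 were joined from shorter runs of shifted neighbouring genes over gaps of up to 60 genes. On chromosome 4 a stretch from IDUA to NFKB1 was delimited, where 230 of 261 genes above the dimmest probe sets were lower, with a median of -0.37, and at -0.35 and -0.39 in replicate pairs 1 and 2. The rest of chromosome 4 was lower too, by less, with 147 of 197 genes lower and a median of -0.126. On chromosome 1, stretches from NBPF8 to JTB (139 genes, median 0.23), from HAPLN2 to CCNQP1 (195 genes, median 0.33) and from GARIN4 to ZBTB18 (135 genes, median 0.24) were higher. Of the 45 genes that fell, 8 lie in the chromosome 4 stretch.

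A candidate explanation for these stretches is DNA copy number that differs between the clones. It stays open: the lowest share of genes on the side of their stretch in a replicate pair was 67.6%, but the stretches were delimited on these arrays, so this largely restates the choice, and no DNA was analysed here. A normalization shift that follows level is argued against as the whole cause, since genes of other chromosomes matched on level had a median of -0.019 (95% of random sets -0.043 to 0.006) for the chromosome 4 stretch and of -0.02 (-0.037 to -0.001) for the chromosome 1 stretches, whose own median was 0.265. The APN form and the clone cannot be told apart, because there is 1 clone per form. The measured change of UBE2K, -4.86, lies well beyond that of the other genes of the stretch, the lowest of which was CXCL8 at -1.903. The genes next to UBE2K above the dimmest probe sets were SMIM14 at -0.131 and PDS5A at -0.647. The shift of the stretch thus does not account for the change of UBE2K as a whole. With 1 probe set of the gene a partial reading cannot be told apart from a change of the whole transcript.

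On chromosome 6, all 9 genes above the dimmest probe sets in a run from H1-2 to H4C5 were lower in L243P, with a median of -1.98, and 6 of them fell. Among them was HFE, a regulator of iron uptake that is not a histone, at 33 and 33 with wild-type APN and 18 and 16, a dim level, with L243P APN. Fewer cells in S phase as the whole cause is argued against by the 46 other replication-dependent histone genes, with a median of -0.176 (quartiles -0.281 and 0.012), although 34 of them were lower and a part of the change stays open, and loss of RNAs without a poly(A) tail by 145 other untailed RNAs, with a median of 0.030. A short loss of DNA in the L243P clone stays open: 9 of 9 genes were lower in each replicate pair, but the run was delimited on these arrays, so this restates the choice, and no DNA was analysed. A change of the run that follows from the APN form was not tested.

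Among the gene lists, without the genes of the stretches of chromosomes 1, 4 and 6, 2 of the 11 called lists lost their call, the NF-kB and inflammatory cytokine list and the histone list, so the stretches do not account for the lists as a whole. The list of early targets of YAP, TAZ and SRF was called then (adjusted p = 0.0416), but had an adjusted p of 0.622 with an estimated correlation over all genes. Dim probe sets near the rounding step are also argued against as the whole cause, since 1 list, that of endoplasmic reticulum stress, lost its call without them. The lists of cholesterol synthesis and of the hypoxia response kept theirs in both cases (adjusted p = 1.62e-15 and 2.76e-11 without the stretches), but not with an estimated correlation, so whether their members moved beyond what 2 cultures per clone share by chance stays open. Clone and APN form remain confounded for them too.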
